A study of Mus musculus with 6 samples.

How the data were processed

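RNA from frozen mouse liver tumours was measured on 1-colour Agilent arrays, 1 tumour per array and 6 arrays in all. The labels put the tumours into 3 groups of 2: Albumin-derived hepatocellular carcinoma (HCC) without CLC, Epcam-derived HCC without CLC, and Epcam-derived HCC with CLC. CLC is a tumour component that the labels name and do not expand. Per the labels, the Albumin-derived tumours came from mice at 90 weeks, and the Epcam-derived tumours from tamoxifen-treated mice fed 0.1% DDC for 8 months. Each labelling reaction started from 0.1 µg of total RNA, per the labels' protocols.

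Spot intensity was extracted with Agilent Feature Extraction 11.5.1.1, per the file headers. The processed signal is an intensity from which the local background was subtracted and spatial and multiplicative trends were removed, with low values replaced by a positive surrogate and no scaling between arrays, per the file headers. Yes or no marks for each spot, such as well above background, saturated or outlier, are other columns of the deposited tables. The authors also gave a table of processed intensity per probe. Each of its columns was the scanner's processed signal times 1 factor per array, so it is an intensity on a linear scale, not centred, and runs in the same direction. The factors were 2.36, 1.91, 1.81, 1.73, 2.42 and 1.64 for Albumin-derived replicates 1 and 2, Epcam-derived without CLC replicates 1 and 2, and Epcam-derived with CLC replicates 1 and 2. The column medians were 61.9, 55.0, 80.0, 74.1, 73.9 and 78.0 in the same order. What set those factors stays unknown.

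Each array held 62976 spots, of which 59305 were not controls and carried 56605 distinct probes. Control spots and outlier spots were left out, the log2 of the processed signal was taken, and the 75th percentile of each array's log2 signal over spots that were not controls was subtracted. Spots of 1 probe were averaged. A probe was kept when it was well above background on both arrays of at least 1 group, with a probe counted as well above background where at least 0.5 of its spots were. That left 34776 probes, and 4 further probes were dropped for an outlier spot. The deposited tables name probes by accession. Accessions without versions were matched to a RefSeq gene table on GRCm38.p6, used for names only because the array design is annotated on mm9, and 32994 probes received 1 of 22911 symbols. The rest kept the name of the deposited table. Where several probes of a symbol passed, as for 5540 symbols, the one with the highest mean over the 6 arrays stood for the gene. The 27412 features tested comprised 15869 with a symbol and 11543 without.

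Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with data.table (version 1.17.8) and jsonlite 2.0.0 for reading. All 6 arrays entered 1 fit with a coefficient per group and 3 residual degrees of freedom, to which eBayes added 2.62 prior degrees of freedom. P-values were two-sided and adjusted by Benjamini-Hochberg over all features, with a threshold of 0.05. Values after ± are standard errors (SE) of a log2 difference unless SD is written. A probe below background on 1 array of a group keeps its measured value there, which holds for Pkia, Rtn4r, Peg3, Eln, Timd4, Cyp4a14, Epcam, Krt19, Bex2, Cyp2b13, Gzmb, Mmp7, B4galnt2 and Nipal2 in at least 1 group. A probe below background on both arrays of a group has only a bound there. Bounds hold for the processed signal alone, since normexp with its offset shrinks differences of dim probes to below them. The bound sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

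Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 28 lists with at least 5 measured genes. Camera asks whether a list's genes differ in their average change from the other genes. Camera with a correlation estimated from the residuals and limma's fry were alternatives. Fry's directional test asks whether a list's genes move, on balance, one way, its mixed test asks whether they change in either direction, and neither compares the list with other genes. The lists covered biliary and ductular, oncofetal and progenitor, hepatocyte secreted and identity, urea cycle and amino acid catabolism, pericentral and Wnt target, cytochrome P450 and xenobiotic, bile acid, heme, NRF2 target, cell cycle, p53 target, extracellular matrix, macrophage and Kupffer, neutrophil, T and NK cell, B and plasma cell, endothelial, erythroid, adipocyte, pancreas and mesothelium, Notch, YAP target, epithelial and mesenchymal transition, interferon response, acute phase and inflammation, fatty acid oxidation and PPARa target, lipid and cholesterol synthesis, glycolysis and hypoxia, and sex-linked and sex-biased genes. They held 650 distinct members, 11 of them in more than 1 list, with 640 on the array and 600 measured.

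The groups, tests, lists and the rule for naming genes were fixed before the data were examined. For each comparison the rule names, among genes past the threshold whose groups did not overlap, the 10 with the largest positive and the 10 with the largest negative difference, leaving out names of clones, accessions and predicted genes. If none passed in a direction, the 5 with the smallest unadjusted p are given as values only. For each list it adds up to 4 members past the threshold, or else the 2 largest differences as values only, and it adds 6 genes throughout, of which Epcam, Alb, Krt19, Sox9 and Afp are reported. Other list members named below were chosen after their values were seen.

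The slide of each array was read from the file headers. Slide 1 held both Albumin-derived tumours and the tumour with CLC replicate 1, and slide 2 held both Epcam-derived tumours without CLC and the tumour with CLC replicate 2. Alternatives were slide as a block, array weights, normexp background correction with an offset of 50, quantile normalization, median centring, the authors' table, no filter on dim probes, a filter on all 6 arrays, the mean of a gene's probes, eBayes with trend and robust, only the 4 arrays compared, the replicate number as a block, and leaving out each array. Normexp was run on the median signal and the median background, because a mean signal is not among the columns. Comparisons within 1 slide, and only features with a symbol, were added after seeing the data. Within 1 slide, or with 1 array of a compared group left out, a group rests on 1 tumour. The same holds for the tumours with CLC with slide as a block. Camera's p-values there do not measure the spread between tumours of that group.

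The code was tested on simulated data with 27412 genes and groups of 2, with 50 genes changed per size in each comparison. For tumours with CLC against Epcam-derived tumours without CLC, 0%, 20%, 96% and 100% of genes changed by a log2 of 1, 2, 4 and 8 were recovered, with 7 calls among 27188 unchanged genes. For Epcam-derived against Albumin-derived tumours without CLC the shares were 0%, 26%, 92% and 100%, with 7 calls among 27189. For tumours with CLC against Albumin-derived tumours they were 2%, 14%, 96% and 100%, with 9 calls among 27188. A list shifted by a log2 of 1 was called in each of the 3 comparisons, and 1, 0 and 0 of the unshifted lists were called in the same order. Simulated genes were drawn independently, while camera's estimated correlations within lists ran from -0.10 (adipocyte, pancreas and mesothelium) to 0.88 (cell cycle) in the data. The simulation therefore cannot show how often camera calls unshifted lists in these data. Each gene was also drawn with its spread after eBayes, which varies less between genes than the measured spread. The shares recovered hold for that spread, and a lack of calls does not exclude large differences. In the data, Cidec differed by 4.31 with against without CLC (limma, adjusted p = 0.999) and was not called. The number of arrays limits the precision.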

Results

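Gene expression was measured in 6 mouse hepatocellular carcinomas, 2 in each of 3 groups. Tumours labelled Albumin-derived arose in mice of a line named for the hepatocyte gene Alb. Tumours labelled Epcam-derived arose in mice of a line named for Epcam, a surface protein of bile duct and ductular progenitor cells, under a diet with DDC, a chemical that blocks heme synthesis and provokes a ductular reaction. The series describes the Epcam-derived tumours as derived from ductular progenitor cells, and 2 of them held a component labelled CLC. The 75th percentile of signal was 285 and 306 for Albumin-derived replicates 1 and 2, 424 and 457 for Epcam-derived without CLC, and 315 and 488 for Epcam-derived with CLC. In the same order, 56.5%, 55.5%, 63.1%, 64.6%, 52.0% and 64.2% of probes were well above background, and 0 spots were saturated. The number of arrays limits the precision.

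Across genes, which are not independent replicates, the correlation of normalised signal ranged from 0.926, between Albumin-derived replicate 2 and Epcam-derived without CLC replicate 2, to 0.978, between Epcam-derived without CLC replicate 2 and Epcam-derived with CLC replicate 2. Replicates of a group correlated at 0.969 (Albumin-derived), 0.957 (Epcam-derived without CLC) and 0.965 (Epcam-derived with CLC). The first principal component held 47.3% of the variance and set the Albumin-derived tumours apart from the other 4, while the second held 18.0% and parted the replicates within each Epcam-derived group.

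**Figure D1:**
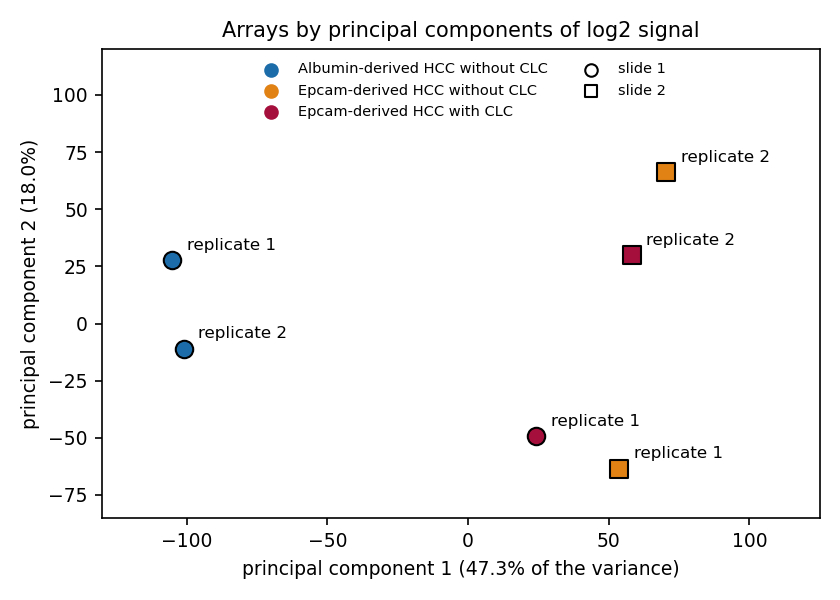
Each point is 1 array, placed by the first principal component (47.3% of the variance) and the second (18.0%) of log2 signal, coloured by group and shaped by slide. The Albumin-derived arrays lie at -105 and -101 on the first component and the 4 Epcam-derived arrays between 24.1 and 70.5.

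Epcam was well above background on 4 arrays and Krt19, a keratin of bile duct cells, on 5. The log2 signal of Epcam was -5.59 and -3.31 in Albumin-derived tumours, the latter being the highest of all arrays. It was -5.61 and -5.18 in Epcam-derived tumours without CLC and -3.69 and -3.86 in those with CLC. The values of -5.59 and -5.61 were not well above background. Alb, the hepatocyte albumin gene, differed by -0.59 ± 0.29 (log2, SE, n = 2) between Epcam-derived and Albumin-derived tumours without CLC. Afp, a fetal liver gene often active in liver cancer, differed by -1.67 ± 1.05 (SE, n = 2) and Sox9, a transcription factor of ductular cells, by 0.87 ± 0.57 (SE, n = 2) in that comparison. None of Epcam, Alb, Krt19, Sox9 and Afp passed limma's threshold over all genes in any of the 3 comparisons.

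The comparison of Epcam-derived tumours with and without CLC asks what goes with that component among tumours of 1 labelled origin and diet. Pericentral and Wnt target genes, which mark the hepatocytes around the central vein and respond to beta-catenin, rose as a list in the tumours with CLC, with a median log2 difference of 1.19 and 19 of 21 measured members higher. That call was lost with an estimated correlation between genes (camera adjusted p = 0.653). Genes of bile duct cells rose as well, with a median of 0.77 and 22 of 30 members higher (adjusted p = 0.653 with an estimated correlation). Lipid and cholesterol synthesis genes rose by a median of 0.78, with 26 of 27 higher (adjusted p = 0.653 with an estimated correlation). No single gene passed the threshold.

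Among pericentral genes, Lgr5, a receptor that amplifies Wnt signalling, was at least 4.73-fold higher with CLC and not well above background without it. Cyp2e1, a cytochrome P450 that oxidises ethanol, differed by 2.04 ± 0.35 (log2, SE, n = 2), a fold of 4.10. Lgr5 and Cyp2e1 were the 2 members that passed when adjusted over the list alone (limma, adjusted p = 0.0147 for each), and neither passed over all genes (0.792 and 0.925). Sp5, a Wnt-induced transcription factor, was at least 3.55-fold higher and not well above background without CLC. With normexp the log2 differences of Lgr5 and Sp5 were 0.78 and 0.60, under those bounds. Differences were 2.26 ± 0.75 (SE, n = 2) for the secreted protein Lect2, 1.54 ± 0.46 for cyclin D1 (Ccnd1), 1.48 ± 0.42 for the transcription factor Tbx3, 1.19 ± 0.36 for ornithine aminotransferase (Oat) and 0.85 ± 0.46 for glutamine synthetase (Glul). The list's camera adjusted p was 1.45e-13, and adjusted p = 0.653 with an estimated correlation. With slide as a block, which here rests on the 1 tumour with CLC on slide 2, the median was 0.95, the same as within slide 2. Camera's p in those fits does not measure the spread between tumours with CLC. Over all 22 alternatives the median ran from 0.78 to 1.54. Camera's adjusted p ran from 4.63e-16 to 0.653, and that of fry, which does not compare a list with other genes, was 0.677.

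Among biliary genes, St14, which encodes the epithelial protease matriptase, differed by 3.45 ± 0.50 (log2, SE, n = 2), a fold of 10.9, and Krt19 by 2.56 ± 0.50 (SE, n = 2), a fold of 5.89. Those were the 2 members that passed when adjusted over the list alone (limma, adjusted p = 0.0191 and 0.0403), against 0.729 and 0.999 over all genes. Differences were 2.75 ± 1.09 (SE, n = 2) for the tetraspanin Tspan8, 1.63 ± 0.53 for the duct keratin Krt7, 1.62 ± 0.73 for Epcam and -0.54 ± 0.57 for Sox9. Epcam signal was higher on Albumin-derived replicate 2, which has no CLC, than on either array with CLC. The trefoil peptide Tff2 went the other way at -2.07 ± 1.22 (SE, n = 2). The list's camera adjusted p was 2.33e-07, and adjusted p = 0.653 with an estimated correlation. The median was 0.64 with dim values set at their bounds, and 0.81 with slide as a block, which again rests on 1 tumour with CLC. Over 22 alternatives the lowest median was 0.35, with normexp. Camera's adjusted p ran from 1.53e-11 to 0.653, and fry's was 0.948.

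Lipid synthesis members included Elovl6, a fatty acid elongase, at 1.44 ± 0.64 (log2, SE, n = 2), Fdps, which makes farnesyl diphosphate, at 1.34 ± 0.50, acetyl-CoA carboxylase (Acaca) at 1.18 ± 0.44 and Pnpla3, a lipase of lipid droplets, at 2.15 ± 1.43. The list's camera adjusted p was 1.25e-12, and adjusted p = 0.653 with an estimated correlation. Its median was 0.39 with slide as a block, which is also the value without the tumour with CLC replicate 1 (adjusted p = 4.40e-05). 0 of its genes passed when adjusted over the list alone or over all genes, with 7 at an unadjusted limma p under the threshold. Against Albumin-derived tumours the lipid list's median was -0.82 for Epcam-derived tumours without CLC and -0.08 for those with CLC. The rise here and that fall of -0.82 share the same 2 tumours without CLC, so they are not separate results. Fatty acid oxidation genes rose by a median of 0.55, with 23 of 25 higher (camera adjusted p = 2.37e-06; adjusted p = 0.819 with an estimated correlation). Fabp1, the liver fatty acid carrier, differed by 1.73 ± 0.64 (SE, n = 2) and Cyp4a14, an inducible fatty acid hydroxylase, by 2.37 ± 1.34. That call did not hold without the tumour with CLC replicate 1, where the median was -0.02 (adjusted p = 0.555), nor with slide as a block or within slide 2, at the same median (adjusted p = 0.555 and 0.457). The highest median with 1 array left out was 0.93.

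Macrophage and Kupffer cell genes rose by a median of 0.48, with 19 of 24 higher (camera adjusted p = 2.38e-04; adjusted p = 0.653 with an estimated correlation), and by 0.42 with slide as a block (adjusted p = 3.58e-04). Without Epcam-derived replicate 1 the median was 0.24, and the call held (adjusted p = 0.0336). Marco, a scavenger receptor of Kupffer cells, differed by 2.28 ± 0.82 (log2, SE, n = 2) and Timd4, a receptor for dying cells, by 1.97 ± 0.81. T and NK cell genes rose by a median of 0.51, with 16 of 21 higher (camera adjusted p = 6.84e-04; adjusted p = 0.819 with an estimated correlation). Cd8a, of cytotoxic T cells, differed by 1.89 ± 0.89 (SE, n = 2), while Klrb1c, an NK cell receptor, was at least 1.65-fold lower and not well above background with CLC. Interferon response genes rose by a median of 0.47, with 23 of 23 higher (camera adjusted p = 6.84e-04; adjusted p = 0.823 with an estimated correlation), led by the chemokine Cxcl9 at 1.31 ± 0.59 (SE, n = 2). The medians were 1.05 for T and NK cell genes (adjusted p = 5.32e-10) and 1.26 for interferon genes (adjusted p = 1.11e-15) with slide as a block. Both calls rested on single tumours. Without the tumour with CLC replicate 2 the medians were 0.17 and -0.47 (adjusted p = 0.493 and 0.470), without Epcam-derived replicate 2 the T and NK cell adjusted p was 0.0730, and without Epcam-derived replicate 1 the interferon adjusted p was 0.992. The interferon call was also lost with no filter on dim probes (0.0929). With 1 array left out the medians reached 1.05 for T and NK cell genes and 1.26 for interferon genes.

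Smaller shifts were called for acute phase genes, with a median of 0.25 and 20 of 27 higher (camera adjusted p = 0.0112; 0.819 with an estimated correlation), for genes of the epithelial and mesenchymal transition, 0.11 and 11 of 20 (0.0223; 0.823), and for extracellular matrix genes, 0.11 and 17 of 28 (0.0223; 0.874). Saa2, an acute phase serum amyloid, differed by 1.94 ± 0.97 (log2, SE, n = 2), Mmp7, a matrix protease of ductular cells, by 1.72 ± 0.62, and elastin (Eln) by 1.35 ± 0.57. The 3 medians were 0.56 (adjusted p = 7.31e-04), -0.03 (0.154) and 0.28 (0.00204) with slide as a block. The acute phase call was lost without the tumour with CLC replicate 2 (median 0.26, adjusted p = 0.345) or Epcam-derived replicate 2 (0.16, 0.188). The transition list's call was lost without the tumour with CLC replicate 1 (-0.03, 0.154) or Epcam-derived replicate 2 (-0.21, 0.926), and the matrix list's without Epcam-derived replicate 2 (-0.46, 0.207) or the tumour with CLC replicate 2 (-0.04, 0.312). All 3 calls were also lost with no filter on dim probes (adjusted p = 0.312, 0.338 and 0.522), with normexp (0.0756, 0.124 and 0.0714) and with only features with a symbol (0.0559, 0.0871 and 0.0974), and the transition and matrix calls with a filter on all 6 arrays (0.247 and 0.0858). Of 22 alternatives the calls were kept in 15, 12 and 14. The highest medians with 1 array left out were 0.56, 0.64 and 0.89 for the 3 lists.

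The other 18 lists did not pass in this comparison, with adjusted p from 0.0810 to 0.977. Median log2 differences were -0.18 for urea cycle genes, 0.40 for cell cycle, 0.04 for heme, 0.12 for neutrophil, 0.46 for B and plasma cell, 0.27 for sex-linked and sex-biased, 0.10 for YAP target, 0.06 for glycolysis and hypoxia, -0.21 for oncofetal, -0.17 for NRF2 target, -0.07 for bile acid, -0.08 for hepatocyte and -0.02 for erythroid genes. The median of cytochrome P450 genes was -0.02 against a mean of 0.18, that of endothelial genes -0.14 against 0.10, and for Notch (-0.10, mean -0.08) and p53 target genes (-0.04, mean -0.11) camera gave the opposite sign. Adipocyte, pancreas and mesothelium genes had a median of 0.11 and a mean of 1.27, because Cidec, a lipid droplet protein, Cfd, the adipocyte protease adipsin, and Msln, a mesothelial surface protein, passed when adjusted over the list alone (limma, adjusted p = 0.0235, 0.00538 and 0.0235). Cps1, the entry enzyme of the urea cycle, differed by -1.64 ± 0.33 (SE, n = 2).

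Over all features limma called 0 genes between Epcam-derived tumours with and without CLC. At an unadjusted p under the threshold there were 954, 358 higher and 596 lower, where chance gives 1371, and every alternative also called 0. The groups did not overlap for 30.1% of genes, against 33.3% by chance, and the smallest adjusted p was 0.651. The genes with the smallest p were Tmem139, a membrane protein (at least 8.02-fold higher), Nipal2, a magnesium transporter relative (at least 2.01-fold), Umod, uromodulin (at least 3.31-fold), all not well above background without CLC, then Pkia, an inhibitor of protein kinase A, at 2.16 ± 0.27 (log2, SE, n = 2; well above background on 1 of 2 arrays without CLC) and the acyltransferase Mboat1 at 2.60 ± 0.36. In the other direction stood the neuropeptide gene Npb at -2.62 ± 0.29 (SE, n = 2), the olfactory receptor Olfr68 (at least 4.24-fold lower), the Nogo receptor Rtn4r at -4.36 ± 0.60 (well above background on 1 of 2 arrays with CLC), lipoprotein lipase (Lpl) at -1.75 ± 0.26 and the homeobox gene Dlx5 (at least 1.26-fold lower). Lists past the threshold numbered 16 with slide as a block and 17 within slide 2, against 10, and without the tumour with CLC replicate 1 or Epcam-derived replicate 1 there were 16.

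The comparison of Epcam-derived with Albumin-derived tumours without CLC asks whether tumours differ by the labelled cell of origin. Targets of NRF2, the regulator of antioxidant genes, rose as a list in the Epcam-derived tumours, with a median log2 difference of 1.22 and 22 of 24 members higher (adjusted p = 0.955 with an estimated correlation), led by the carbonyl reductase Cbr3 at 5.78 ± 0.61 (SE, n = 2). Hepatocyte secreted and identity genes fell, with a median of -0.61 and 25 of 32 lower, and lipid and cholesterol synthesis genes fell, with a median of -0.82 and 22 of 27 lower. All 3 calls were lost with an estimated correlation (camera adjusted p = 0.955 for each). The Epcam-derived tumours compared here are also the reference for the lipid rise with CLC, so that rise and the lipid fall here are not separate results. Among single genes, the sperm-tail filament gene Tekt5 was at least 131-fold higher and the carboxylesterase Ces4a at least 802-fold lower, each not well above background in its dim group. Origin, diet and tamoxifen differ together between these groups, and each group lies on a slide of its own. An age is given for the Albumin-derived tumours alone, and the sex of the animals is not given.

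Among genes that rose, Cbr3 was 55.1-fold higher (limma, adjusted p = 0.0475) and Ugt1a10, a glucuronosyltransferase whose near-identical Ugt1a relatives make its identity uncertain, 31.7-fold higher at 4.99 ± 0.35 (log2, SE, n = 2; 0.0234). Npb rose by 4.15 ± 0.29 (SE, n = 2), a fold of 17.8 (0.0234), and Mcc, a gene mutated in colorectal cancers, by 3.35 ± 0.32, a fold of 10.2 (0.0417). The prostaglandin receptor Ptgfr was at least 3.41-fold and Vwa7 at least 4.64-fold higher (0.0475 and 0.0417), both not well above background in the Albumin-derived group. With normexp the log2 differences of Ptgfr and Vwa7 were 0.62 and 0.70, under those bounds, and their calls were kept in 5 and 6 of 18 alternatives. The adjusted p of Tekt5 was 0.0234, and its lowest difference, with normexp, was 4.53.

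Among genes that fell, Cyp3a44, uncertain among near-identical Cyp3a genes, was at least 2433-fold lower (limma, adjusted p = 0.0417) and Ces4a had an adjusted p of 0.0234. Anxa8, a calcium-binding annexin, differed by -10.11 ± 0.76 (log2, SE, n = 2; 0.0249), the glycosyltransferase B4galnt2 by -9.05 ± 0.49 (0.0206), with another probe at -5.45, and Krt23, a keratin of stressed liver and ducts, by -7.12 ± 0.72 (0.0443). The difference was -7.10 ± 0.45 (SE, n = 2; 0.0234) for the cytochrome oxidase subunit Cox6a2, -5.26 ± 0.49 (0.0408) for the vomeronasal receptor Vmn2r4 and -4.51 ± 0.45 (0.0417) for Apcs, the acute phase protein serum amyloid P. Agr2, a mucus-cell disulfide isomerase, was at least 61.9-fold, Nipal2 at least 26.4-fold and the amylase Amy2b at least 14.1-fold lower (0.0417, 0.0117 and 0.0417), all not well above background in the Epcam-derived group. With normexp the log2 differences were smaller than the bounds, at -8.40 for Cyp3a44, -6.71 for Ces4a, -3.34 for Agr2, -2.39 for Nipal2 and -1.82 for Amy2b. Over the 18 or 19 alternatives of each gene named here the calls were kept in 7 to 13.

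The NRF2 list had a camera adjusted p of 2.51e-06, and adjusted p = 0.955 with an estimated correlation. Adjusted over the list alone 13 members passed, against 1 over all genes. They included Gpx2, a glutathione peroxidase, at 5.56 ± 1.21 (log2, SE, n = 2), the cystine carrier Slc7a11 at 5.07 ± 1.38, the quinone reductase Nqo1 at 2.91 ± 0.47 and Gclc, which starts glutathione synthesis, at 2.43 ± 0.54. The hepatocyte list had an adjusted p of 4.63e-05 (adjusted p = 0.955 with an estimated correlation), and adjusted over the list alone 8 members passed as lower and 1 as higher, against 0 over all genes. The complement gene C8b differed by -2.75 ± 0.31 (SE, n = 2), the fibrinogen chain Fga by -2.26 ± 0.48, and Hpd, an enzyme of tyrosine breakdown, by 2.61 ± 0.43. The lipid list had an adjusted p of 4.91e-05 (adjusted p = 0.955 with an estimated correlation) and 0 genes adjusted over the list alone, with Fdps at -2.55 ± 0.50 (SE, n = 2). Macrophage genes rose, with a median of 0.97 and 21 of 24 higher (camera adjusted p = 0.0207; adjusted p = 0.955 with an estimated correlation) and the receptor Cx3cr1 at 2.73 ± 0.69 (SE, n = 2).

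With slide as a block, which links both groups only through the tumours with CLC, the medians were 1.60 for the NRF2 list (adjusted p = 5.02e-07), -0.34 for the hepatocyte list (0.0554), -0.36 for the lipid list (0.852) and 0.69 for the macrophage list (0.0250). No slide held both groups, so no value within a slide can be given. The macrophage call was lost without Albumin-derived replicate 1 (median 0.68, adjusted p = 0.121) or Epcam-derived replicate 2 (0.63, 0.115), and with the authors' table (1.28, 0.0944). The hepatocyte call was lost with quantile normalization, where the median of -0.21 was the smallest over 21 alternatives (adjusted p = 0.0542). The number of lists called was 4, against 8 without Albumin-derived replicate 1 or Epcam-derived replicate 2, 7 without Albumin-derived replicate 2 and 6 without Epcam-derived replicate 1.

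The other 24 lists had adjusted p from 0.263 to 0.844. Camera's sign differed from the median for biliary genes (median 0.27, mean 0.23, camera lower), glycolysis (0.27, 0.12, lower), urea cycle (-0.03, mean 0.33, higher), neutrophil (-0.04, 0.19, higher) and cell cycle genes (-0.07, 0.05, higher). It differed from the mean for bile acid (median -0.22, mean 0.00, camera lower), B and plasma cell (0.57, -0.06, higher) and pericentral genes (-0.15, 0.04, lower). Biliary members went both ways: adjusted over the list alone 3 passed as higher and 3 as lower, with the secreted protein Wfdc2 at 4.91 ± 1.24 (log2, SE, n = 2), Tff2 at least 22.0-fold higher and not well above background in the Albumin-derived group, the protease inhibitor Spint1 at -2.88 ± 0.45 and St14 at -2.35 ± 0.50, and over all genes 1, Krt23, passed. Cyp1a2, a dioxin-inducible cytochrome P450, differed by 3.95 ± 0.61 (SE, n = 2) and Cyp2e1 by -1.62 ± 0.35, and both passed when adjusted over the pericentral list alone (limma, adjusted p = 0.0183 and 0.0435).

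Over all features 67 genes passed between Epcam-derived and Albumin-derived tumours without CLC, 16 higher and 51 lower, of which 43 carried a symbol. At an unadjusted p under the threshold there were 5482, where chance gives 1371, and their balance was the opposite, 3212 higher and 2270 lower, and the groups did not overlap for 55.2% of genes, against 33.3% by chance. Limma called 0 with slide as a block, with 1995 at an unadjusted p under the threshold, and all 67 kept their sign. A kept sign is a weak check, because the genes were called from these same arrays for differences large against their spread. Leaving out Albumin-derived replicate 1 or 2, or Epcam-derived replicate 1 or 2, gave 0 calls (smallest adjusted p 0.118, 0.117, 0.0881 and 0.113, with 3569, 3785, 3905 and 4441 unadjusted), and leaving out either tumour with CLC gave 16.

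**Figure D2:**
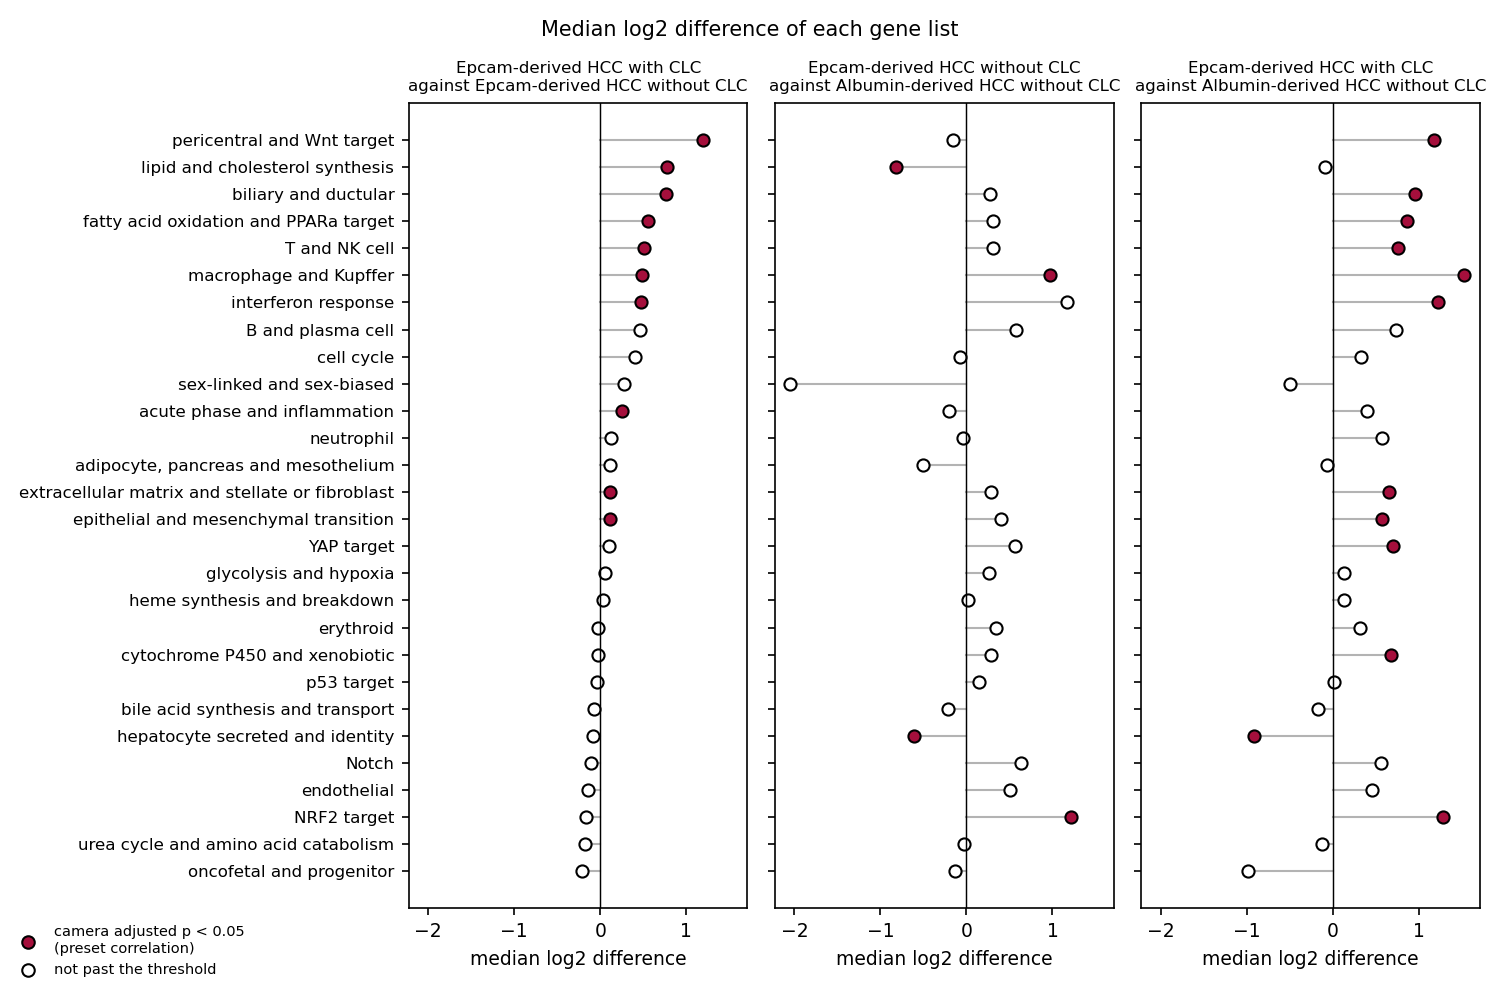
Median log2 difference of each of 28 gene lists in the 3 comparisons, 1 point per list, filled where camera with the preset correlation passed the threshold. Filled points number 10, 4 and 12 from left to right, and none is called with an estimated correlation.

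The comparison of Epcam-derived tumours with CLC with Albumin-derived tumours sets apart the groups that differ in origin, diet, tamoxifen and CLC together, with age given for the Albumin-derived tumours alone and sex for neither group. NRF2 targets rose with a median log2 difference of 1.28 and 22 of 24 higher, macrophage genes with 1.53 and 19 of 24, and pericentral genes with 1.18 and 20 of 21 (adjusted p = 0.701 for each with an estimated correlation). Hepatocyte genes fell, with a median of -0.92 and 25 of 32 lower (0.701 with an estimated correlation). Both groups also entered a comparison above, the Albumin-derived tumours as the same reference. Genes and lists called there and again here are therefore not separate results. The pericentral median was 0.67 without Albumin-derived replicate 2 and 1.65 without replicate 1, and the call held in both (adjusted p = 0.00142 and 1.02e-09). Tekt5 was at least 76.6-fold higher and Ces4a at least 512-fold lower, each not well above background in its dim group (limma, adjusted p = 0.0416 and 0.0278). With normexp the log2 differences of Tekt5 and Ces4a were 3.75 and -6.71, under those bounds, and their calls were kept in 7 and 8 of 19 alternatives.

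The other genes with a symbol that passed were lower in the tumours with CLC. B4galnt2 differed by -9.80 ± 0.49 (log2, SE, n = 2; limma, adjusted p = 0.0266), with another probe at -5.44, and was well above background on 1 of 2 arrays with CLC. Over 19 alternatives the difference of B4galnt2 ran from -10.39 to -6.51, and its call was kept in 8. Cox6a2 differed by -7.11 ± 0.45 (0.0340). Gnat2, a transducin of cone cells, differed by -5.36 ± 0.36 (SE, n = 2; 0.0340), the galactosyltransferase B3galt1 by -4.09 ± 0.30 (0.0368) and the gastrokine Gkn3 by -3.72 ± 0.25 (0.0340). The difference was -3.72 ± 0.29 (SE, n = 2; 0.0416) for Nipal2, well above background on 1 of 2 arrays with CLC, and -3.20 ± 0.26 (0.0460) for Lpl, which releases fatty acids from lipoproteins. In all 17 genes passed, 3 higher and 14 lower, 12 of them with a symbol, while 4388 had an unadjusted p under the threshold, 2179 higher and 2209 lower, where chance gives 1371. The groups did not overlap for 50.8% of genes, against 33.3% by chance. Signs kept in the settings below are not a separate check, since the genes were called from these same arrays for differences large against their spread. With slide as a block, within slide 1, and without any 1 of the 6 arrays, limma called 0 (3293, 3473 and 3108 to 4310 unadjusted; smallest adjusted p 0.114, 0.213 and 0.0633 to 0.170), and all 17 kept their sign in each.

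The NRF2 list had a camera adjusted p of 2.71e-07, the macrophage and pericentral lists 2.22e-06 and the hepatocyte list 7.04e-06, each with adjusted p = 0.701 with an estimated correlation. Adjusted over the list alone 10, 6 and 5 members passed as higher in the first 3, and 14 passed as lower and 1 as higher in the hepatocyte list, against 0 over all genes. They included Cbr3 at 5.19 ± 0.61 (log2, SE, n = 2), Gpx2 at 4.80 ± 1.21, the microglia and macrophage receptor Cx3cr1 at 2.80 ± 0.69, Adgre1, which encodes the macrophage marker F4/80, at 1.69 ± 0.30, Oat at 2.25 ± 0.36, Cyp1a2 at 3.55 ± 0.61 and C8b at -3.09 ± 0.31. Cd163, a haemoglobin scavenger receptor, was at least 4.25-fold higher and not well above background in the Albumin-derived group. Medians of the NRF2, macrophage, pericentral and hepatocyte lists with slide as a block were 1.40 (adjusted p = 1.87e-07), 1.32 (3.15e-06), 1.07 (3.63e-05) and -0.67 (0.00186). The hepatocyte median was smallest with quantile normalization, at -0.46 (0.00642).

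Biliary genes rose by a median of 0.96, with 22 of 30 higher (camera adjusted p = 0.00715; adjusted p = 0.701 with an estimated correlation). Adjusted over the list alone 3 passed as higher, Wfdc2 at 7.36 ± 1.24 (log2, SE, n = 2), the secretin receptor Sctr, at least 2.26-fold and not well above background in the Albumin-derived group, and Krt19 at 2.75 ± 0.50, and 1 as lower, Krt23 at -5.32 ± 0.72, against 0 over all genes. The median was 0.85 with slide as a block (adjusted p = 0.0449), and without Albumin-derived replicate 1 it was 0.40 (0.268). It was smallest with normexp, at 0.30 (0.00212). Cytochrome P450 genes rose by 0.68, with 19 of 28 higher (0.0311; 0.701 with an estimated correlation), by 0.97 with slide as a block (0.00724), and the call was lost without Albumin-derived replicate 2 (0.08, 0.302) or the tumour with CLC replicate 1 (0.42, 0.349). YAP target genes rose by 0.70, with 17 of 25 higher (0.0376; 0.701 with an estimated correlation). With slide as a block, or without the tumour with CLC replicate 2, their median was 0.34 (0.280), and without Albumin-derived replicate 1 the adjusted p was 0.636. With the authors' table the biliary, cytochrome P450 and YAP target calls were all lost (adjusted p = 0.0823, 0.232 and 0.163), as were cytochrome P450 with the replicate number as a block (0.0738) and YAP target within slide 1 (0.0783). With 1 array left out the medians reached 1.60 for biliary, 1.14 for cytochrome P450 and 0.98 for YAP target genes.

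Interferon genes rose by a median of 1.22, with 20 of 23 higher (camera adjusted p = 1.42e-04; adjusted p = 0.701 with an estimated correlation), and the antiviral gene Oasl1 differed by 3.08 ± 0.77 (log2, SE, n = 2). T and NK cell genes rose by 0.76, with 16 of 21 higher (0.00715; 0.701 with an estimated correlation), and the killer-cell protease Gzmb at 2.06 ± 0.26 (SE, n = 2) was the 1 gene that passed when adjusted over the list alone. With slide as a block, or without the tumour with CLC replicate 2, the medians were 0.32 (adjusted p = 0.0756) and 0.18 (0.191), and within slide 1 the adjusted p was 0.0108 and 0.173. The T and NK cell adjusted p was 0.0635 without Albumin-derived replicate 2. Extracellular matrix genes rose by 0.66, with 24 of 28 higher (0.00715; 0.711 with an estimated correlation), and transition genes by 0.58, with 13 of 20 higher (0.00777; 0.701 with an estimated correlation). Mmp7 at 4.20 ± 0.62 (SE, n = 2) passed when adjusted over the transition list alone. With slide as a block the medians were 0.51 (0.0501) and 0.76 (0.00638), and within slide 1 the matrix list's adjusted p was 0.0329. Without Albumin-derived replicate 1 they were 0.19 (0.397) and 0.12 (0.112), without the tumour with CLC replicate 2 the matrix median was 0.51 (0.0501), and without the tumour with CLC replicate 1 the transition median was 0.71 (0.0673). With 1 array left out medians ran from 0.32 to 2.33 for interferon, 0.18 to 1.18 for T and NK cell, 0.19 to 1.02 for matrix and 0.12 to 1.18 for transition genes, the interferon median of 2.33 being that without the tumour with CLC replicate 1.

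Fatty acid oxidation genes rose by a median of 0.86, with 21 of 25 higher (camera adjusted p = 2.15e-04; adjusted p = 0.701 with an estimated correlation), and by 1.24 with slide as a block (3.30e-09). Acot1, a thioesterase induced by fatty acids, differed by 2.95 ± 0.90 (log2, SE, n = 2). Without Albumin-derived replicate 2 the median was 0.32 (adjusted p = 0.0635), and without the tumour with CLC replicate 1 the adjusted p was 0.295. The highest median with 1 array left out was 1.31. The other 16 lists had adjusted p from 0.0879 to 0.976. The median, mean and camera sign differed for lipid synthesis (-0.08, 0.07, lower) and for adipocyte, pancreas and mesothelium genes (-0.06, 0.69, higher). With an estimated correlation none of the 10, 4 and 12 lists called in the 3 comparisons passed, and fry called 0 in each, with 2, 4 and 4 at an unadjusted p under the threshold.

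**Figure D3:**
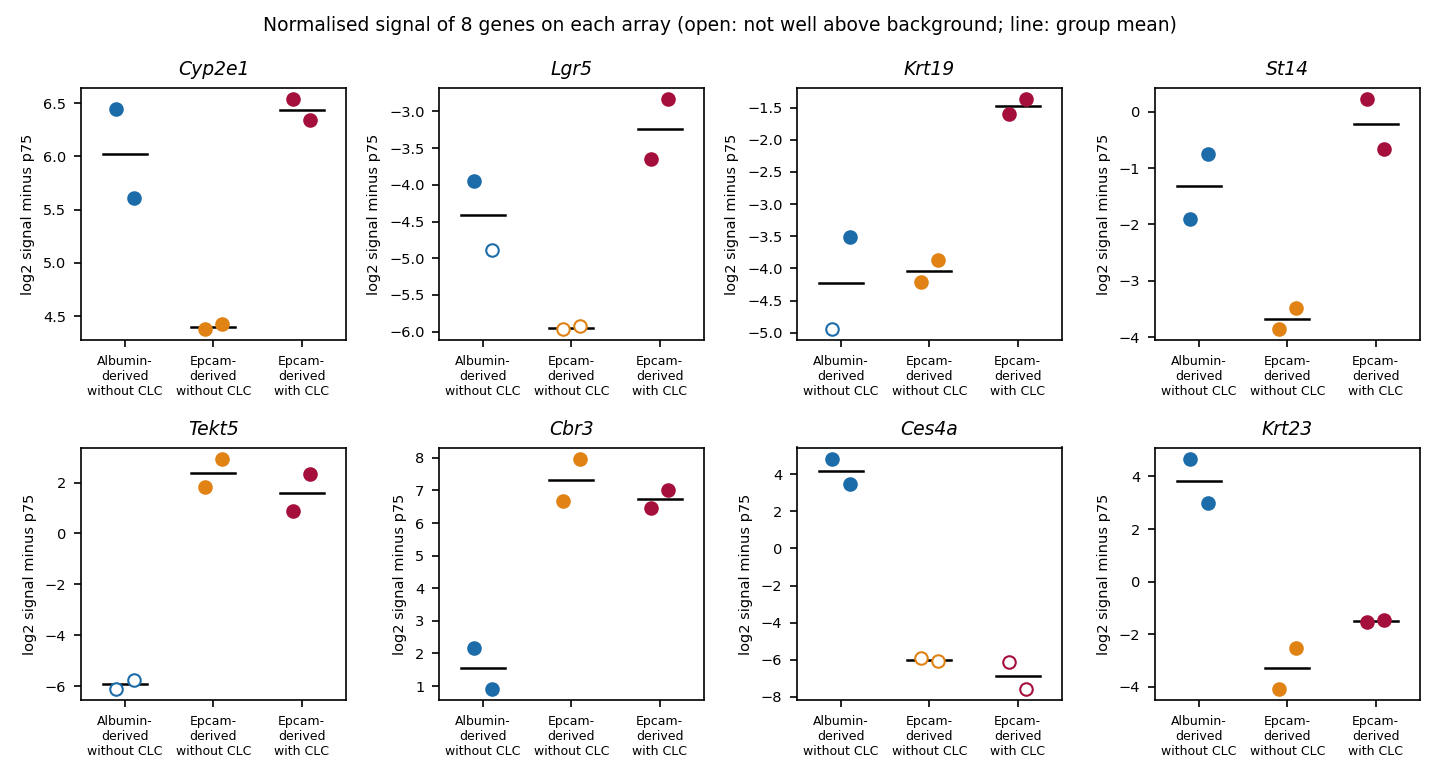
Log2 signal minus the array's 75th percentile for 8 genes, 1 point per tumour in each of 3 groups, with open points where the probe was not well above background and a line at the group mean. St14 has means of -3.67 without and -0.22 with CLC among Epcam-derived tumours, and Ces4a a mean of 4.17 in Albumin-derived tumours.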

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

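Comparisons within 1 slide and only features with a symbol were chosen after seeing the data. Below, "CLC" is Epcam-derived tumours with against without CLC, "origin" is Epcam-derived against Albumin-derived tumours without CLC, and "combined" is tumours with CLC against Albumin-derived tumours. No gene was called for CLC in any alternative, with 524 to 2460 at an unadjusted limma p under the threshold.

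For origin, 67 genes became 135 with normexp (39 of the same genes), 102 with quantile normalization (56), 106 with median centring (67), 129 with the authors' table (67) and 110 with the mean of a gene's probes (66). With a filter on all 6 arrays, which tests fewer genes, 32 passed, among them all 29 of the 67 that it still tested. The rest of the 67 had no usable probe well above background on all 6 arrays. With only features with a symbol 40 passed, with only the 4 arrays compared 16 (12 the same) and without a filter on dim probes 1. The authors' table called 63 higher and 66 lower, or 48.8% higher against 23.9%. For combined, 17 became 66 with normexp (15), 66 with quantile normalization (17), 35 with median centring (17), 27 with trend and robust (15), and 1 without a filter on dim probes. Limma called 0 with only the 4 arrays compared (4310 unadjusted), and 0 with slide as a block (3293) or within slide 1 (3473). Slide as a block called 0 for origin (1995). The cause was not tested, except that the 4 arrays or a block leave 2 residual degrees of freedom and a single slide leaves 1.

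Leaving out 1 array gave 0 to 16 genes for origin (16 without either tumour with CLC, 0 without any of the other 4) and 0 to 0 for combined; a lone array is assumed to vary like the other groups, with 2 residual degrees of freedom. All 67 and all 17 kept their sign in each, which is not a separate check. The genes were called from these same arrays for differences large against their spread. Leaving out a tumour with CLC cannot change an origin difference. Lists called ran from 9 (without Epcam-derived without CLC replicate 2) to 16 (without replicate 1 of either Epcam-derived group) for CLC and from 4 to 8 for origin. Medians ran from -0.21 to 0.64 for transition, -0.46 to 0.89 for matrix and -0.47 to 1.26 for interferon genes for CLC. Camera's direction reversed for these 3 with 1 tumour left out: Epcam-derived without CLC replicate 2 for transition and matrix, with CLC replicate 2 for interferon. Medians also turned negative, with camera's direction kept, for transition and fatty acid oxidation without the tumour with CLC replicate 1, and for matrix without replicate 2.

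An estimated correlation called 0 lists for CLC, 0 for origin and 0 for combined, as did fry (0, 0 and 0), against 10, 4 and 12. Slide as a block gave 16 lists for CLC (17 within slide 2) and 13 for origin. Normexp gave 13 lists for origin and no filter 10. The cause was not tested. For CLC the pericentral, biliary, lipid and macrophage lists, and for combined the NRF2, macrophage, pericentral and hepatocyte lists, kept their call in 20 of 22 alternatives, all but those 2. For origin the NRF2 list kept it in 19 of 21, the lipid list in 18, the hepatocyte list in 17 and the macrophage list in 16. Every alternative that kept a list's call used camera with the preset correlation, and those 2, which did not, lost all calls. Some alternatives also repeat a fit. Using only the arrays compared gave the same values as leaving out either array of the remaining group. For CLC and combined, slide as a block gave the same values as leaving out a tumour with CLC. Counts of alternatives, here and above, are therefore not counts of separate checks.

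Among scalings and filters, the median of all genes moved to -0.16 (origin) and -0.12 (combined) with normexp, 0.37 and 0.31 with the authors' table, and -0.18 and -0.14 with no filter, from 0.06 and -0.01.

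The replicate number as a block called 11 genes for origin (10 the same) and 0 for combined (4273 unadjusted). Deviations of same-numbered tumours correlated across genes at -0.16 (Albumin-derived and Epcam-derived without CLC), 0.06 (Albumin-derived and with CLC) and 0.23 (both Epcam-derived groups), so the numbers do not establish pairs. Scan date was not run separately, because all arrays share 1 scan day. Between 52.0% and 64.6% of probes per array were well above background, which limits what was tested.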

Other observations

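The fit with slide as a block was planned before the data were examined, and its use as a test of explanations, like all other tests in this part, was chosen only after the results were seen.

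The higher pericentral and biliary genes in Epcam-derived tumours with CLC were weighed against technical causes. A difference between slides as the whole cause is argued against by the fit with slide as a block, where the pericentral median was 0.95 against 1.19 without the block (camera adjusted p = 2.68e-13) and the biliary median 0.81 against 0.77 (adjusted p = 2.18e-09). Over the alternatives camera's adjusted p ran from 4.63e-16 to 0.653 for the pericentral list and from 1.53e-11 to 0.653 for the biliary list, and fry, which does not compare a list with other genes, gave 0.677 and 0.948. The block value rests on 1 tumour with CLC set against both tumours without CLC on slide 2. Among those tumours only Epcam-derived without CLC replicate 1 had low Y-linked signal, so the block is not balanced for a sex effect. Differences between single tumours stay open. The 4 Epcam-derived tumours make 3 splits into pairs, too few to decide, and the largest median in the other splits was 0.21 for pericentral genes, against 1.19, and 0.29 for biliary genes, against 0.77. Surrounding liver in the tumours with CLC also stays open, because the hepatocyte list, which such tissue would raise, had a median of -0.0805 (adjusted p = 0.756) with members going both ways. A hypothesis that remains is that the CLC component itself may carry both programmes. Against Albumin-derived tumours, which have no CLC, the same 2 tumours with CLC were also higher in both lists, with medians of 1.18 and 0.96 (camera adjusted p = 0.701 for each with an estimated correlation). That comparison reuses these tumours and differs in origin, diet and tamoxifen too, so it is not separate support. The biliary call there was lost with the authors' table and without Albumin-derived replicate 1, where the median was 0.40. Epcam-derived tumours without CLC did not pass the threshold as lists against Albumin-derived tumours (-0.15, with 10 of 21 higher, and 0.27, with 18 of 30 higher). Of the 4 genes that passed over a list alone, Krt19 had the same order, and Cyp2e1, St14 and Lgr5 in at least 1 Albumin-derived tumour lay near a tumour with CLC. Cyp2e1 was 6.45 and 5.61 in Albumin-derived tumours, 4.38 and 4.42 in Epcam-derived tumours without CLC, and 6.54 and 6.34 with CLC. St14 was -1.90 and -0.75, -3.85 and -3.48, and 0.22 and -0.66 in the same order. Lgr5 was -3.94 and -4.88, -5.96 and -5.93, and -3.64 and -2.83 in that order, where -4.88, -5.96 and -5.93 were not well above background. For Cyp2e1, St14 and Lgr5 the Epcam-derived tumours without CLC were the lowest, and what sets their level was not tested. No table here tests the hypothesis, which would take the CLC component measured apart from the rest of the same tumours.

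The 67 genes that differed between Epcam-derived and Albumin-derived tumours without CLC lie on different slides, so slide was weighed through the tumour with CLC on slide 1. On a scale where the Albumin-derived mean is 0 and the Epcam-derived mean is 1, that tumour had a median position of 0.777 (SD 0.213 over genes), and the tumour with CLC on slide 2 had 0.896. That value cannot decide for the 67 genes, because both tumours with CLC entered the fit that called them, and 0% of simulated genes that follow slide alone were called in 1000 draws. Over the 16 genes called from the 4 arrays compared, where the tumours with CLC took no part, the median position was 0.810 (SD 0.193) and 16 of 16 lay past halfway, the lowest at 0.572. A slide effect as the whole cause is argued against for those 16, of which 12 are among the 67, on the value of 1 tumour, and stays open for the rest. Different floors of dim probes as the whole of these differences were argued against too: with every value raised to its array's lowest detected value, 66 of 67 genes kept a log2 difference over 1, and the remaining one had 0.41. The raised values were not fitted again, so whether the calls depend on the floors stays open. Of the 67, 1 was called with no filter on dim probes and 39 with normexp. Origin, diet and tamoxifen cannot be told apart, because they change together between the groups, and none of them was tested alone. Age, given for the Albumin-derived tumours alone, and sex, not given, stay open too, and 1 of 2 Epcam-derived arrays against 0 of 2 Albumin-derived arrays lacked Y-linked signal. The 67 genes include Tekt5, Cbr3, Ces4a and Krt23. The lysosomal protease Ctsl, chosen after its value was seen, differed by -2.82 ± 0.26 (log2, SE, n = 2; limma, adjusted p = 0.0408).

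Y-linked signal was low on 1 array of each Epcam-derived group, without CLC replicate 1 and with CLC replicate 1, and the labels give no sex. No Y-linked probe was well above background on the former, and on the latter only that of Uty was, at -3.13, which stays unexplained. Eif2s3y, a Y-linked translation factor gene, had a log2 signal relative to the 75th percentile of 1.47, 1.01, -7.39, 1.26, -6.02 and 1.09 on Albumin-derived replicates 1 and 2, Epcam-derived without CLC replicates 1 and 2 and Epcam-derived with CLC replicates 1 and 2, where the values of -7.39 and -6.02 were not well above background. Xist, the transcript of the inactive X chromosome, had -3.11, -6.74, -0.95, -7.42, -0.08 and -7.77, and was well above background on Albumin-derived replicate 1 and on both arrays with low Y-linked signal. Dim arrays are argued against: over 6 Y-linked probes with dim values raised to the array's lowest detected value, the median fall against the other arrays of the slide was at least -1.87 on 1 of those arrays and -3.28 on the other, where the median of all features moved by -0.04 and 0.05. Loss of the Y chromosome alone is argued against by Xist, whose lower value on those 2 arrays lay 2.16 above the highest of the other 4. Male tissue mixed into the tumour with CLC replicate 1 is argued against by Eif2s3y, which, raised in the same way, lay -5.31 from its slide's other arrays while Uty lay -1.33 from them, a gap of -3.98 in log2 as a bound. Beyond loss of the Y chromosome and mixed tissue no biological explanation was tested, since sex is not among the groups. Apart from Uty, both arrays have the values that female animals would give. On the other array of each Epcam-derived group Y-linked signal was present and Xist was not well above background. The second principal component parted the same arrays, at -63.5 and -49.2 against 66.2 and 29.8. Each Epcam-derived group holds 1 array with low Y-linked signal, so a sex effect would be balanced between these groups where all 4 arrays are compared. It would not be balanced with slide as a block, within slide 2 or with an Epcam-derived array left out. Both Albumin-derived arrays carry Y-linked signal, and replicate 1 of them carries Xist as well.

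Genes known for sex-biased expression in liver varied widely. Cyp2b9 and Cyp2b13, cytochromes P450 that are higher in female liver, differed by -5.35 ± 3.92 and -5.36 ± 3.24 (log2, SE, n = 2) between Epcam-derived and Albumin-derived tumours without CLC. Cyp4a12a, a male-biased fatty acid hydroxylase, differed by 2.40 ± 2.98 (SE, n = 2) and the urinary pheromone gene Mup20 by 2.24 ± 1.34 between Epcam-derived tumours with and without CLC.

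Replicates of a group differed in cell cycle and interferon genes. The median log2 difference of cell cycle genes was -1.66 between Epcam-derived without CLC replicates 1 and 2, -1.32 between the tumours with CLC and 1.32 between the Albumin-derived tumours. For interferon response genes the medians were -1.22, -1.45 and 0.75 in the same order. In both Epcam-derived groups the lower array is replicate 1, which is also the array with low Y-linked signal. The interferon median with against without CLC was 0.35 between replicates 1 and 0.61 between replicates 2, but 2.00 for replicate 2 with CLC against replicate 1 without, and -0.90 the other way round. With 1 tumour on each side these values have no replicate check.

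Oncofetal genes, active in fetal liver and in many liver cancers, did not pass the threshold as a list, and large differences with wide errors included Bex2, a neuronal and progenitor gene, at -7.09 ± 1.47 (log2, SE, n = 2; well above background on 1 of 2 Epcam-derived arrays) and the RNA-binding protein Igf2bp3 at -3.18 ± 1.14 between Epcam-derived and Albumin-derived tumours without CLC. H19, an imprinted noncoding RNA, differed by -3.26 ± 3.20 (SE, n = 2) and the imprinted gene Peg3 by -2.67 ± 1.08 with CLC against without. Genes of the heme pathway, which DDC disturbs, did not pass as a list in Epcam-derived against Albumin-derived tumours without CLC, with 9 of 17 higher, 8 lower and a median of 0.02 (camera adjusted p = 0.812). They ran from -1.26 to 2.99, and members chosen after their values were seen included biliverdin reductase B (Blvrb) at 2.99 ± 0.38 (SE, n = 2) and Alas1, the first enzyme of heme synthesis, at 1.49 ± 0.37 in Epcam-derived against Albumin-derived tumours without CLC. Blvrb passed when adjusted over the list alone (limma, adjusted p = 0.00488), against 0.0586 over all genes.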
